A study of Rattus norvegicus with 6 samples.

How the data were processed

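RNA sequencing was analysed for 6 libraries of primary rat bone marrow mesenchymal stem cells (bone marrow stromal cells that can give rise to bone, cartilage and fat cells), 3 cultured on titanium dioxide nanotubes of 100 nm and 3 on a smooth surface, each for 6 hours. Per the labels' protocols, RNA was extracted with Trizol and 3 µg of total RNA entered a NEBNext Ultra RNA library preparation. Groups were taken from the surface given in the labels. The titles number the first 2 libraries of each surface, and the last library of each carries no number there. The deposited table numbers these libraries 3, and that number is used here only as a name. The labels do not say whether the libraries of a surface came from separate cultures or animals, so the p-values measure the spread between these libraries, which may be technical.

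The authors deposited 1 table of FPKM values (fragments per kilobase of gene model, scaled by the library total) for 19458 genes, with 1 column per library and no pooled column. Bowtie 1.0.1, HISAT2 2.1.0 and HTSeq are named, without their roles, per the submitters' processing notes. The same notes name the mouse builds mm10 and GRCm38, while all 19458 identifiers in the table are rat Ensembl genes. The rat build and annotation release, the strand setting and any filter are not given in the sources used here. Reads of near-identical gene copies and of overlapping or antisense genes are therefore not separable from these values. No gene of the table is at 0 in all 6 libraries.

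The table pairs no identifier with a gene symbol, and 0 of the 19458 identifiers occur in the reference gene table used here, which lists 47357 rat genes by symbol without Ensembl identifiers. Gene symbols, genome positions and functions are therefore not given. The gene lists for stromal, bone, fat and cartilage markers, adhesion, stress and other cell types that were fixed before the data were examined were not tested, and the rule for named genes, which works on symbols, was not applied. In its place at most 2 identifiers per direction are printed: the genes with the smallest unadjusted p among those whose groups did not overlap and whose higher group mean was at least 2 FPKM (the first such higher gene and the first 2 lower ones on nanotubes), with the other place for a higher gene given to the single gene called when 1 library was left out instead of to the second such higher gene. ENSRNOG00000008855 is printed in addition, only as an example of a low gene. All were chosen after their values were seen.

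Whole reads were worked out from the FPKM values. An FPKM value is the read count times a constant over gene-model length and library total, so the most frequent ratio between columns among low values gives the ratio of the totals, and each gene's values then give the smallest whole-number reads and length. All 116748 values (100%) gave whole reads within a relative tolerance of 1e-12, and the reads summed to between 99.74% and 99.77% of the totals. Genes whose reads and length share a common factor come out with too few reads, so a recovered length can be a fraction of the true one. Whether such genes make up all of the remainder was not tested. With 1 library total shifted by 1 read, 15.2% of 2000 genes still gave whole reads. On simulated reads, with the true total of the first simulated library given, 99.25% of 2936 genes were recovered exactly. The absolute size of the totals was therefore not tested by that simulation. The totals were 17624390, 17286106 and 16950168 reads for nanotube libraries 1, 2 and 3, and 16299799, 16770616 and 17382519 for smooth libraries 1, 2 and 3. A tested gene had a median of 486 reads per library. These reads set the counting error and were not the basis of the main test.

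The comparison of surfaces used limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(FPKM + 1) of all 6 libraries. It covered the 11865 genes with a mean of at least 1 FPKM, without rescaling, at a Benjamini-Hochberg adjusted p of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. On simulated data with the real depths and spread, 200 of 11847 genes were changed, and the fit called 53.5% of those changed 2-fold and 74.7% of those changed 4-fold, with 6 unchanged genes also called. With a low dispersion of 0.01 it called 97.5% of the changed genes and 20 unchanged ones. That simulation drew genes independently.

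Libraries were compared over the 12157 genes with a mean of at least 20 reads. The squared difference of a gene's share of reads was divided by its counting variance and averaged over genes, so that 1 is the value of libraries that differ by counting error alone. Each library was also fitted as a linear mix of every pair of other libraries, with the residual expressed the same way. Intervals based on reads cover counting error only. Other settings fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, no trend, library weights, a replicate block, a 2-fold limit and leaving out each library. Added after the data were seen were limma's voom on the recovered reads, removal of a trend with gene length, a fit without either library numbered 3, and the splits and library differences with libraries left out. Python 3.11.15 with numpy 2.4.6 was used for the recovery of reads.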

Results

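The transcriptome of rat bone marrow mesenchymal stem cells was measured 6 hours after they were placed on titanium dioxide nanotubes of 100 nm or on a smooth surface, with 3 libraries per surface. Each library held between 16299799 and 17624390 counted reads. Between 16549 and 16753 of the 19458 listed genes had a value above 0 in a library. The libraries differed in how far a few transcripts dominated. The 10 most abundant genes took 13.61%, 10.05% and 8.35% of the reads in nanotube libraries 1, 2 and 3, and 11.38%, 7.97% and 9.34% in smooth libraries 1, 2 and 3.

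The design asks which genes respond early to the nanotube surface. No gene of the 11865 tested differed between the surfaces at an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment, lowest adjusted p 0.753, n = 3 libraries per surface). At an unadjusted p under 0.05 there were 724 genes, 202 with a higher and 522 with a lower mean on nanotubes. If p-values were spread evenly, 593 would be expected. Of the 10 ways to split the 6 libraries into groups of 3, 3 gave at least 724 such genes (exact permutation p = 0.3, one-sided, smallest possible 0.1). The median over the splits was 258, and the highest other split gave 3606. The voom fit on the recovered reads also called 0 genes and gave 724 at an unadjusted p under 0.05. Without the filter on low values, limma called 0 of 19458 genes, with a lowest adjusted p of 0.0572. The imbalance of direction depended on scaling. Higher genes made up 27.9% of those at an unadjusted p under 0.05 as deposited and 41.0% of 921 such genes after median-of-ratios scaling, which moved the median log2 fold change of all tested genes from -0.04 to 0.01. All 3 nanotube values lay above all 3 smooth values in 560 genes and below them in 889 genes. Together these were 12.2% of the tested genes, against 10% by chance. After median-of-ratios scaling the split was 859 above and 888 below.

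Differences between the surface means were small for most genes. The log2 fold change of nanotubes over smooth lay between -0.46 and 0.36 from the 5th to the 95th percentile. On the log2(FPKM + 1) scale the means differed by 2-fold or more in 94 genes, 48 higher and 46 lower on nanotubes. This count leaves out low genes whose mean FPKM differed by more than that, such as ENSRNOG00000008855 (2.16 ± 1.32 FPKM on nanotubes and 0.50 ± 0.04 on smooth, SD, n = 3 libraries each). For 10193 genes (85.9%) the 95% interval of the limma fit lay within a 2-fold change in either direction, and for 6690 genes it lay within 1.5-fold. These intervals are on the log2(FPKM + 1) scale, which understates the change of low genes. They also take every library as labelled and as independent. Nanotube library 3 lay close to smooth library 2 but not to smooth library 1, and pooled material stays a hypothesis for smooth library 3 (both below). The intervals therefore do not show that the surfaces were equivalent. The median width of these intervals was 0.38 on the log2 scale to each side. The spread within a surface exceeded the counting error. The median SD of a gene was 0.21 log2 units among nanotube libraries and 0.15 among smooth libraries, against 0.06 from counting alone.

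The genes with the smallest unadjusted p values did not pass the adjustment. ENSRNOG00000032740 had 1.93 ± 0.04 FPKM on nanotubes and 7.31 ± 1.78 on smooth (SD, n = 3 libraries each), a log2 fold change of -1.48 with a standard error of 0.18 and a limma adjusted p of 0.753. It rested on 24 reads in the nanotube and 89 reads in the smooth libraries, a ratio of 0.262 (exact 95% counting interval 0.16 to 0.416). ENSRNOG00000056183 had 0.58 ± 0.25 and 2.85 ± 0.62 FPKM (SD, n = 3 libraries each). It rested on only 4 and 19 reads, a ratio of 0.205 (0.0507 to 0.616). ENSRNOG00000002403 was higher on nanotubes, with 46.4 ± 2.9 against 27.9 ± 3.9 FPKM (SD, n = 3 libraries each). Its log2 fold change was 0.72 with a standard error of 0.13, from 8725 and 5112 reads, and its limma adjusted p was also 0.753.

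Nanotube library 3 decided the value of another gene. ENSRNOG00000017484 had 18.8 and 17.2 FPKM in nanotube libraries 1 and 2, but 1.11 FPKM in nanotube library 3. The smooth libraries had 1.43, 1.37 and 1.51 FPKM. Over all 6 libraries its log2 fold change was 1.90 with a standard error of 0.83 and a limma adjusted p of 0.753. Without nanotube library 3 it was 2.96 with a standard error of 0.11, and this was the single gene called in that fit, at a limma adjusted p of 0.00704. That fit gave 2207 genes at an unadjusted p under 0.05, against 724 with all libraries. Leaving out any other single library gave between 235 and 534 such genes.

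**Figure D1:**
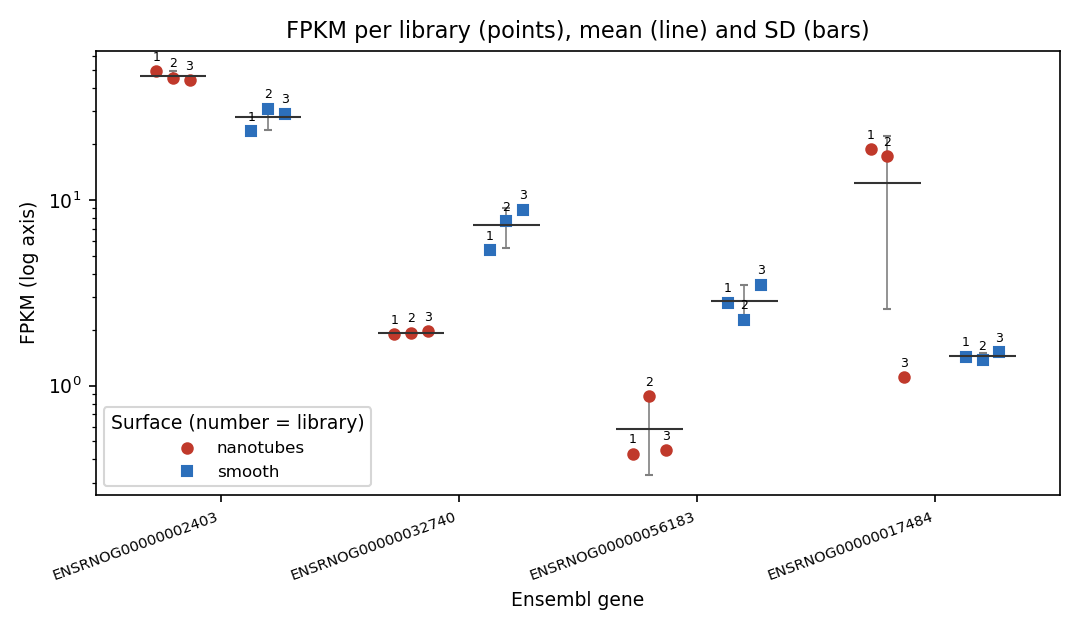
FPKM (log axis) of 4 rat Ensembl genes in the 3 nanotube libraries (circles) and the 3 smooth libraries (squares), with the library number above each point, the mean as a line and the SD as bars. ENSRNOG00000017484 is at 18.8 and 17.2 FPKM in nanotube libraries 1 and 2 and at 1.11 FPKM in nanotube library 3, close to the smooth libraries.

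With all 6 libraries, the surfaces did not separate the libraries as wholes, and the measures of separation changed with both libraries numbered 3. The difference between surfaces held 20.3% of the variance of log2(FPKM + 1) over the tested genes, against a mean of 20% over all 10 ways to split the 6 libraries into groups of 3. As many as 4 of the 10 splits gave at least that share (exact permutation p = 0.4, one-sided, smallest possible 0.1). Without nanotube library 3 the share was 39.6%, against a mean of 25% over the 10 splits of the 5 libraries left, and no other split was as large (highest other 38.3%, exact permutation p = 0.1, the smallest possible). With each other library left out in turn the share was 18.2% to 25.9% (exact permutation p from 0.3 to 0.7). Without either library numbered 3 it was 37.3%, against a mean of 33.3% over the 3 splits and 34.6% for the highest other split (exact permutation p = 0.333, the smallest possible), and 1046 genes were at an unadjusted p under 0.05. Mean squared differences between libraries averaged 68.2 times the counting variance for the 6 pairs from the same surface and 68.0 times for the 9 pairs from different surfaces. Without the pairs of nanotube library 3 they averaged 49.6 times for 4 pairs and 85.2 times for 6 pairs, and without the pairs of either library numbered 3 they averaged 76.8 times for 2 pairs and 89.9 times for 4 pairs. These values with libraries left out were looked at after the positions of the libraries were seen.

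**Figure D2:**
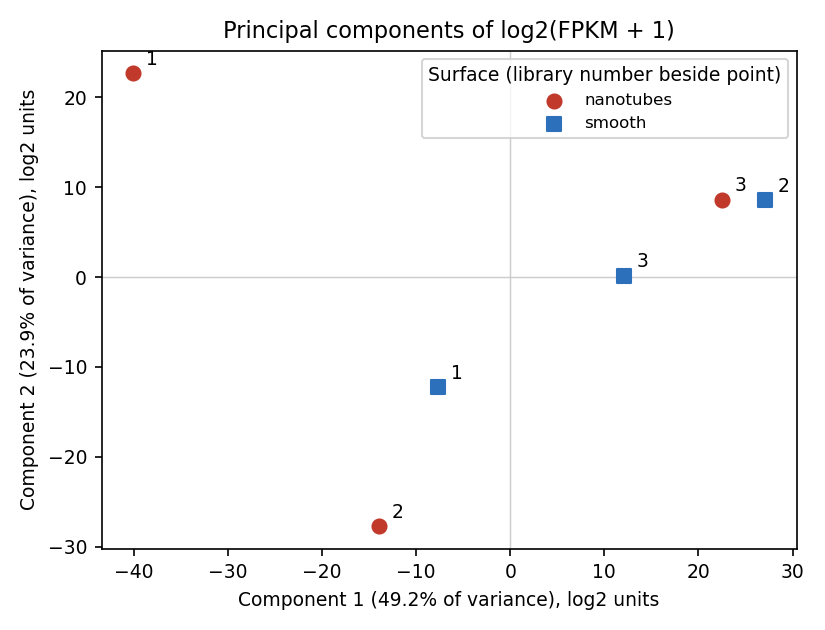
First and second principal components of log2(FPKM + 1) over the tested genes, holding 49.2% and 23.9% of the variance, for nanotube (circles) and smooth (squares) libraries with their numbers. Nanotube library 3 (22.55 on component 1) lies beside smooth library 2 (27.07), while nanotube libraries 1 and 2 lie at -40.07 and -13.98. Smooth library 1 lies at -7.63, on the side of nanotube libraries 1 and 2. On component 2 nanotube libraries 1 and 2 lie far apart, at 22.65 and -27.71.

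The closest pair crossed the surfaces. Nanotube library 3 and smooth library 2 differed by 6.73 times the counting variance. Between them, 86 of the 11865 tested genes were 2-fold or more apart on the log2(FPKM + 1) scale. Nanotube library 3 differed from nanotube libraries 1 and 2 by 132 and 78.6 times, with 786 and 613 genes 2-fold or more apart. Its difference from smooth library 1 was 74.4 times, with 551 such genes. Nanotube libraries 1 and 2 differed from each other by 75.8 times. Nanotube library 1 was nearer to smooth library 1, at 67.45 times. Nanotube library 2 was nearer to smooth libraries 1 and 3, at 59.6 and 58.2 times. Smooth libraries 1 and 2 differed by 77.9 times, with 590 such genes. Smooth library 3 stood between these, at 25.3 times from smooth library 1 and 19.4 times from smooth library 2.

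**Figure D3:**
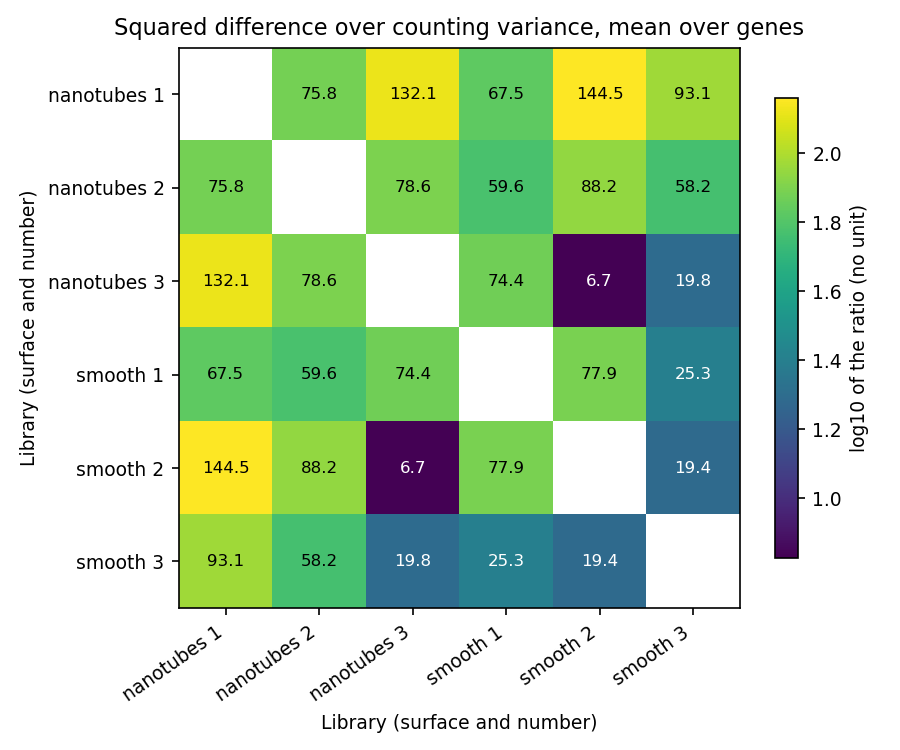
Mean squared difference between libraries over its counting variance, for each pair of the 6 libraries over 12157 genes (the number in each cell, coloured on a log10 scale, with 1 for libraries that differ by counting error alone). The lowest value, 6.7, is between nanotube library 3 and smooth library 2, and the highest, 144.5, is between nanotube library 1 and smooth library 2.

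Genes marked out nanotube libraries 1 and 2 as a pair more often than all 3 nanotube libraries together. In 21 genes both nanotube libraries 1 and 2 lay at least 2-fold above every other library, and in 10 genes at least 2-fold below, on the log2(FPKM + 1) scale. Only 1 gene set all 3 nanotube libraries at least 2-fold apart from all smooth libraries, ENSRNOG00000032740, which was lower on nanotubes. Among the other 14 pairs of libraries, the next highest total was 15 genes, all of them lower in nanotube library 3 and smooth library 2 than elsewhere. These counts have no test.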

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

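The fit with voom, the removal of a length trend and the fit without either library numbered 3 were chosen after the data were seen. Of 20 alternatives, 18 kept 0 genes changed between the surfaces. The 2-fold limit is among these, and could only give 0 because it narrows the calls of the main fit. Library weights gave 1567 genes (405 higher, 1162 lower, 4261 at an unadjusted p under 0.05). That fit gave smooth library 3 a weight of 163, against at most 0.969 for any other library, and the weight estimate stopped before converging. Leaving out 1 library gave 0 to 1 genes changed and 0 to 1 higher, the 1 being ENSRNOG00000017484 without nanotube library 3. The genes at an unadjusted p under 0.05, 724 with all libraries, ranged from 235 (without smooth library 3) to 2207 (without nanotube library 3), and were 409 and 379 without nanotube libraries 1 and 2 and 425 and 534 without smooth libraries 1 and 2. The share of variance between the surfaces, 20.3% with all libraries, ranged from 18.2% (without smooth library 3) to 39.6% (without nanotube library 3). Without either library numbered 3 it was 37.3%, against a mean of 33.3% over the 3 splits, with 1046 genes at an unadjusted p under 0.05 and 0 changed. The replicate block on the same 4 numbered libraries gave 1355 genes at an unadjusted p under 0.05 and 0 changed at the same 37.3%, and the block on all 6, whose last level the labels do not state, gave 801 and 0. Deviations from the group means correlated at 0.32 for number 1, -0.21 for number 2 and 0.06 for number 3, so the numbers were not taken to pair the libraries. The 3 genes described with all libraries kept their direction in every alternative in which they were tested, and passed the threshold with library weights alone. They had been chosen as genes whose groups did not overlap, so a kept direction was nearly fixed in advance and is no support for them. edgeR and DESeq2, planned for a table of counts, were not run on these FPKM values.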

Other observations

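The tests of 1 library sequenced repeatedly, of a wrong label, of pooled material, of summed reads, of library depth, of the size of the differences after scaling and of the splits of the libraries were chosen after the result was seen. The distances, mixes and calls of each split had been looked at before any test here was written, and 3 tests were altered after their first result. The first correction for gene length also removed each library's overall level, which acts as a rescaling, and left 0 genes called, against 652 in the version used. A correlation of differences of 0.099 was first read as excluded by its bound of 0.1, and then as open because the resampling interval spans that bound. The test of a few abundant genes was divided into the number called and the size of the differences once 0 calls had been seen.

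Nanotube library 3 lay nearer to smooth library 2 than to its own group, and repeated sequencing of 1 library is argued against by their difference of 6.73 times the counting variance. A wrong label on this library stays open: over the 200 genes with the smallest p in the fit without it, its median position was 0.12 (quartiles 0.02 and 0.24), where 0 is the smooth mean and 1 the nanotube mean, while nanotube libraries 1 and 2, left out in turn, lay at 0.97 (0.24 and 1.45) and 0.72 (0.27 and 1.12). The distances between the libraries had already implied a position near 0, so it does not decide between a wrong label and a preparation shared with smooth library 2, and the position does not return every label, since smooth library 2, left out with nanotube library 3 counted as nanotube, lay at 0.53 (0.31 and 0.82). A swap with smooth library 1 cannot be told apart from no swap. Smooth library 1 lay at 0.27 (quartiles 0.07 and 0.43), with it and nanotube library 3 left out of the choice of genes, where a swap needs above 0.75. Smooth library 3 helped set the smooth mean and the choice of genes. It lay close to a mix with 45% smooth library 1 (below), so this position was not independent of smooth library 1. The labelling after that swap is the split that called the most genes (713, below). Whether nanotube library 3 shares a surface difference with the others also stays open: its difference from smooth library 2 correlated across genes, which are not independent replicates, at Pearson 0.099 (0.068 to 0.129 on resampling genes) and Spearman 0.19 with the difference of nanotube libraries 1 and 2 from smooth library 1.

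Smooth library 3 lay between smooth libraries 1 and 2 in 93.4% of the 923 genes 2-fold or more apart between them, at a median position of 0.45 (quartiles 0.37 and 0.54). Nanotube library 3 lay between nanotube libraries 1 and 2 in 64.1% of 999 such genes. Here 2-fold was taken on reads plus 1, scaled by the library totals, over 12157 genes. The counts of genes 2-fold apart in the Results are on log2(FPKM + 1) over the tested genes. A sum of the deposited reads is argued against, because a mix of 45% smooth library 1 and 55% smooth library 2 left a residual of 2.42 times the counting variance and a simulated pool 1.02 times. That residual was the lowest of 60 mixes of library pairs and below the 3.3 times of a mix on the log scale. The simulated pool drew new reads from the linear mix. Its 1.02 times is therefore also the value for pooled material that differs by counting error alone. The residual of 2.42 times argues against such a pool as well. Pooled material of smooth libraries 1 and 2 with variance beyond counting error is kept as a hypothesis, which these values do not single out. The next lowest residual, 4.08 times, was also for smooth library 3, from nanotube library 3 and smooth library 1 at weights of 0.55 and 0.45. Smooth library 3 was about as far from nanotube library 3 (19.8 times) as from smooth library 2 (19.4 times). The residual of the linear mix had been seen before its bound of 3 was set, so only the comparison with the log scale could have come out otherwise. With pooled material the smooth group would hold fewer than 3 independent samples, and its SD would be too small.

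Another split of the 6 libraries called more genes than the surfaces did: the real split called 0, 1 of the others 713 and the remaining 8 called 0. With a real count of 0 all 10 splits give as many by necessity, so this count does not decide whether the real one is chance. The split of nanotube libraries 1 and 2 with smooth library 1 against the rest called 116 genes higher and 597 lower and held 42% of the variance, and the share of the 10 most abundant genes follows it, at 10.05% to 13.61% on that side against 7.97% to 9.34% on the other. Gene length is argued against by a Spearman correlation of 0.06 with the fold change across genes, and depth by totals of 16.3 to 17.62 M reads on one side, overlapping the 16.77 to 17.38 M reads on the other. The number of calls may depend on a few abundant genes, since median-of-ratios scaling left 0 genes called (limma lowest adjusted p 0.0521, against 0.0327), but it moved the median log2 fold change of all tested genes only from -0.12 to 0.00, which is too small a shift to account for the size of the differences: the 597 lower genes, chosen for being lower, had a median of -0.67 (quartiles -0.99 and -0.53, median SE 0.12) before and -0.55 (-0.87 and -0.40, 0.12) after scaling.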
